A study of Mus musculus with 10 samples.

How the data were processed

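Bulk ATAC-seq peak lists of 10 libraries were used, 1 per library. Per the submitters' processing notes, the tools were fastp 0.23.4, Bowtie2 2.4.5, SAMtools 1.13, MACS2 2.2.9.1 and R 4.4.2, with the mouse build mm39. Peaks were called per library and not on pooled samples, since the authors deposited 1 list for each. The peak calling settings, any shift of reads for the transposase, the removal of duplicate or mitochondrial reads and the genome size setting are not given in the sources used here. Each of these could change which peaks were called. The lowest -log10 q in the lists lay between 1.30 and 1.34.

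In each list deposited by the authors, the fold is the linear ratio of pileup to background at the summit. The deposited p and q values are given as -log10. The score in the deposited lists is 10 times the -log10 q as a whole number. A peak's fold, p, q and score are the authors' own values, and they were used here to describe, rank or filter peaks within 1 list. Peaks that the caller had repeated for several summits were counted once. Chromosomes 1 to 19, X and Y were used.

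The fold and p of each peak were solved together for a whole-number pileup and an expected background, with a pseudocount of 1 in the fold. All peaks of every library (100%) gave a whole number within a relative misfit of 2e-05. The lowest background in a list was taken as its genome-wide rate and the smallest peak width as its fragment length. Above that rate, at least 99.9% of peaks had a background that was a whole multiple, within 0.02 of a step, of fragment length over 10 kb. Background rate over fragment length gave the fragments per kb of effective genome. No total read number follows, because the genome size setting is not given in the sources used here. Depth sets which peaks can be called: the lowest pileup among called peaks was 6 or 7 fragments in the 6 deeper libraries and 2 to 4 in the others, so absence from a shallow list is not absence of open chromatin.

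Group and replicate came from the labels. Comparisons were activated against non-activated nuclei in stressed mice (3 against 3), in standard-reared mice (2 against 2) and in all (5 against 5), stressed against standard-reared in each class (3 against 2) and by animal (3 against 3). Number of peaks and covered length were tested on the log2 scale by two-sided exact permutation over all regroupings, with Benjamini-Hochberg adjustment over the 6 comparisons. Each library was single-animal per the labels. The library names show that replicate numbers pair the same animals in stressed mice. In standard-reared mice activated replicate 2 and non-activated replicate 1 share an animal, so the numbers do not pair there. As a check, libraries of 1 animal had a mean Jaccard index of 0.450 and other activated to non-activated pairs 0.458.

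For regions of 1 group, lists were shortened to the 7076 peaks with the highest -log10 q, the length of the shortest list. Overlapping peaks were merged into regions, and those with a peak in at least 2 libraries were kept, with 1 bp of overlap as presence. Regions present in all libraries of 1 group and none of the other were counted and compared with other splits of the same libraries, at most 100. Named regions were chosen by a rule. For each direction, up to 10 were taken that separated the groups at equal length and overlapped no peak in the whole lists of the other group, ranked by their lowest percentile of -log10 q over the libraries of the group, and the remainder was filled from the whole lists. Regions in all 10 libraries and on sex chromosomes were chosen after their values were seen. Positions are 1-based in mm39.

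The main tests of each comparison, most alternatives and the naming rule were fixed before the data were examined. Further tests and alternatives were chosen later, and the closing section names them. The alternatives were a -log10 q of at least 5, autosomes only, every summit entry, pileups thinned to the lowest background rate at a common -log10 p limit of 4.16 (seed 1), whole lists, other overlap and consensus limits, a paired test and each library left out. Planned results on promoters, 18 gene lists, enrichment of those lists and 15 sequence motifs could not be run, and named genes are not reported. They need an annotation or sequence of mm39, and the gene table at hand is of another build (GRCm38.p6). On simulated data, 100% of 10148 pileups were recovered, and all 100 planted regions per direction were found in the stressed, rearing and pooled comparisons. These regions were planted away from real peaks in lists already cut, so that check covers the counting only, not depth or rank. A simulated thinned library held 98.0% of the peaks of one made at that depth. That cut was milder than the one the activated libraries underwent, and it drew mostly enriched sites rather than a whole genome. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9 were used.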

Results

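Chromatin accessibility was profiled by bulk ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in nuclei of the ventral tegmental area of adult mice (older than postnatal day 60). The ventral tegmental area is a midbrain region that holds dopamine neurons. The mice carried ArcCreERT2, a tamoxifen-dependent recombinase driven by the immediate early gene Arc, together with a Sun1 nuclear envelope tag, and tagged nuclei were separated from the rest on magnetic beads. Mice had been reared under early-life stress or standard conditions, and the labels class each library as activated or non-activated. The 10 libraries came from 6 single animals: 2 standard-reared activated, 3 stressed activated, 2 standard-reared non-activated and 3 stressed non-activated libraries. All 3 stressed animals and 1 of the standard-reared animals gave both classes. Both standard-reared non-activated libraries were from females, whereas the other 3 groups held both sexes.

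Peak lists held between 7076 and 50786 peaks on chromosomes 1 to 19, X and Y. The standard-reared activated libraries had 39783 and 17283 peaks in replicates 1 and 2. The stressed activated libraries had 16374, 19710 and 15128 in replicates 1 to 3. Of the non-activated libraries, the standard-reared ones had 7076 and 14636, and the stressed ones 50786, 12582 and 9008. Peaks covered 2.74 to 20.3 Mb per library. Depth, solved from the lists themselves, was 5.30 to 10.9 fragments per kb of effective genome in the 5 activated libraries. In 4 non-activated libraries it was 0.309 to 1.45, and in stressed non-activated replicate 1 it was 6.52. The 6 deeper libraries also had shorter fragment lengths (134 to 161 bp) than the other 4 (210 to 250 bp), so depth and library type ran almost parallel to activation.

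**Figure D1:**
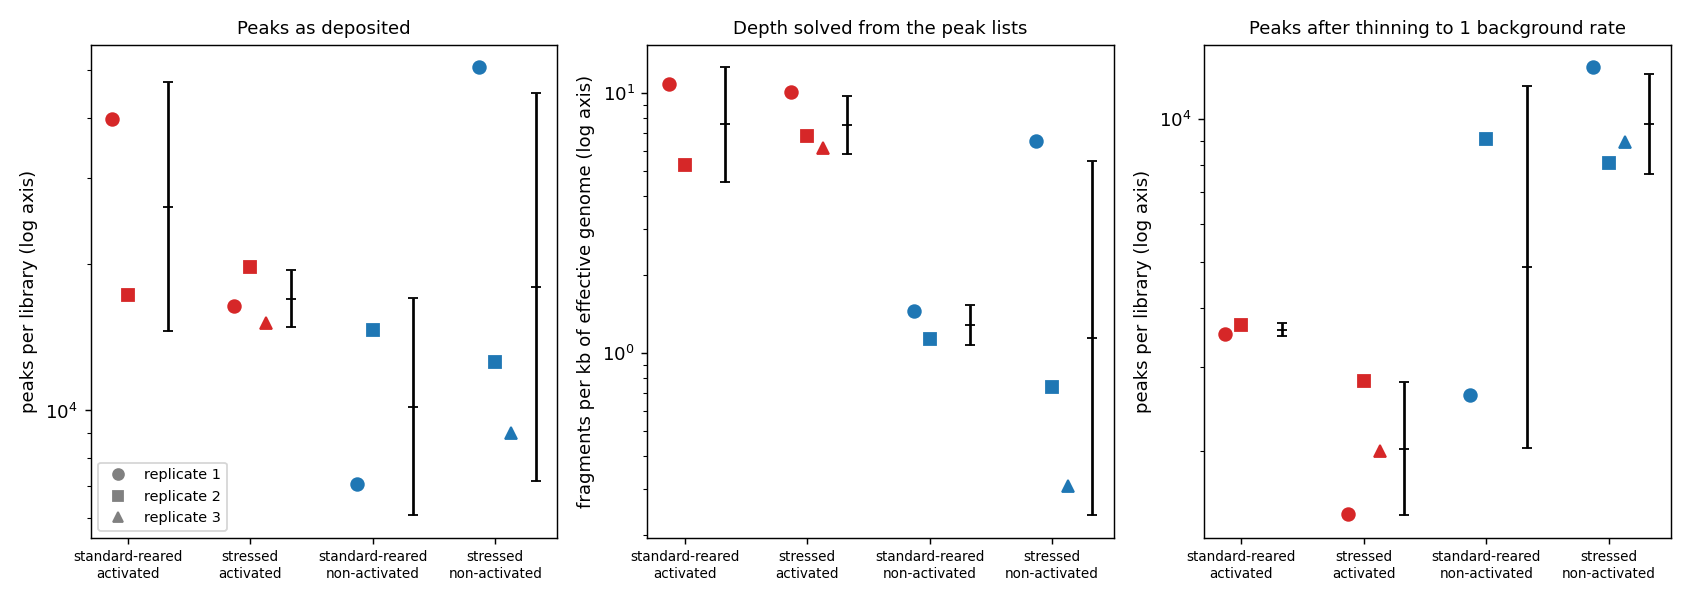
Peaks per library as deposited (left), depth in fragments per kb of effective genome (middle) and peaks per library after pileups were thinned to 1 common background rate (right), all on log axes, for each replicate of the 4 groups (red, activated; blue, non-activated), with the geometric mean and 1 SD on the log2 scale as black bars. As deposited, stressed non-activated replicate 1 had the most peaks (50786); after thinning the 5 activated libraries held 1471 to 3679 peaks and the non-activated ones 2624 to 12848.

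A large set of regions was open in every library whatever the rearing or activation. Merged over the whole lists, 74593 regions had a peak, of which 25437 were found in at least 2 libraries and 5296 in all 10, while 49156 (65.9%) appeared in a single library. Most of the latter came from the 2 longest lists, with 26559 in stressed non-activated replicate 1 and 16407 in standard-reared activated replicate 1, whereas the other 8 libraries had 95 to 1496 each. Among the 7076 strongest peaks of each library, 9730 regions were shared by 2 or more and 2965 by all 10. The region ranked highest in its weakest library lay on chromosome 2 (73216264 to 73217333, mm39), where its peak stood at or above percentile 99.5 of every list. Others near the top were on chromosome 4 (3938220 to 3939308), chromosome 5 (129970223 to 129971414), chromosome 6 (143112361 to 143113627) and chromosome 14 (61676637 to 61677815). Regions are given by position because no gene annotation of mm39 was used here.

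The title of the series concerns the open chromatin of cells activated by early-life stress. The contrast of activated with non-activated nuclei in stressed mice bears on it. Alone, that contrast cannot tell activation by stress from other activation. Which cell types each class held was not examined. Among the strongest peaks, 128 regions were present in all 3 stressed activated libraries and absent from all 3 non-activated ones, and 45 showed the opposite pattern. In the whole lists, 0 of the 128 and 0 of the 45 lacked a peak in every list of the other class. Each thus overlapped a peak in at least 1 of those lists, and in how many was not counted. In the whole lists, 44 regions were called in the activated and 18 in the non-activated libraries only. The highest-ranked activated regions of the whole lists lay near the centromeric ends of chromosome 14 (3050787 to 3051004) and chromosome 9 (3025421 to 3025732), followed by chromosome 8 (71584428 to 71584716), chromosome 1 (162336927 to 162337298) and chromosome 16 (91997590 to 91998117). No filter for repeated sequence was applied here to the deposited peaks. The highest-ranked non-activated regions lay on chromosome 15 (99157588 to 99158083), chromosome 17 (35246230 to 35246706) and chromosome 9 (121200521 to 121200942). Of the 10 ways to split these 6 libraries into 3 and 3, the real one gave 173 regions at equal length and the highest other 197. On the whole lists 8 of the 10 splits gave at least the real 62, with a median of 109 and a maximum of 926 among the others, so the named regions come from a split with fewer regions than most.

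The number of peaks did not differ by more than the replicate spread in that contrast. Stressed activated libraries had a mean log2 number of peaks of 14.05 ± 0.20 (SD, n = 3) and stressed non-activated libraries 14.13 ± 1.32 (SD, n = 3), a ratio of 0.947 (two-sided exact permutation p = 1; the smallest possible is 0.1). Within animals the activated library held 0.322, 1.57 and 1.68 times as many peaks as the non-activated library in replicates 1, 2 and 3. Without stressed non-activated replicate 1 the log2 difference turned to 0.67 and the regions of 1 group rose from 173 to 559. At a common background rate the difference was -2.27 on the log2 scale (exact permutation p = 0.1), with fewer peaks in the activated libraries. That thinning re-tested only peaks called at full depth, and the activated lists were cut most, so the procedure may contribute.

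In standard-reared mice, 534 regions were among the strongest peaks of both activated libraries and neither non-activated library, and 512 showed the reverse. The total of 1046 compares with 343 and 360 for the other 2 splits of these 4 libraries. With 3 splits, no share below 1 of 3 is possible. Both activated libraries were deeper, with shorter fragments, than both non-activated ones, so activation and library type cannot be told apart here. The whole lists gave 2776 and 43 regions. The ratio of peak numbers was 2.58, from mean log2 values of 14.68 ± 0.85 and 13.31 ± 0.74 (SD, n = 2 each; two-sided exact permutation p = 0.333, the smallest that 2 against 2 allows). Thinning to a common background rate turned the log2 difference from 1.37 to -0.44, which rested on non-activated replicate 2, since it was 0.46 without that library. One animal gave a library to each side, and its activated library had 2.44 times as many peaks as deposited and 1.40 times as many after thinning.

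Pooled over rearing, 25 regions were among the strongest peaks of all 5 activated libraries and no non-activated one, and 9 showed the reverse. On the whole lists 7 regions were called in all 5 activated libraries and in no non-activated library, and 0 the other way. That number was not unusual, as 26 of 100 splits into 5 and 5 gave as many, the highest other 209. The 7 lay on chromosome 14 (3050787 to 3051004), chromosome 13 (83880394 to 83880806), chromosome 5 (22452838 to 22453197), chromosome 9 (15539000 to 15539458), chromosome 6 (25460420 to 25461199), chromosome 4 (53384850 to 53385144) and chromosome 16 (77126000 to 77126572). The one on chromosome 14 ranked highest, at percentile 55.8 or above in each activated list, and that on chromosome 16 reached only percentile 2.33 in its weakest list. The chromosome 14 region is the one near the centromeric end that was named for stressed mice. None of the 7 was among the regions that separated the classes at equal list length.

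Activated libraries had 1.41 times as many peaks as non-activated ones, with mean log2 values of 14.30 ± 0.56 and 13.80 ± 1.10 (SD, n = 5 each). That difference was within the spread of the libraries (two-sided exact permutation p = 0.397; adjusted p = 0.794 over 6 comparisons). Covered length gave a ratio of 1.41 (exact permutation p = 0.413). The direction turned when depth was thinned to a common background rate. Activated libraries then had fewer peaks, by -1.54 on the log2 scale (exact permutation p = 0.0317, over free regroupings of the libraries). Thinning re-tested only peaks called at full depth, and it cut activated lists from background rates of 0.805 to 1.64. Peaks that a library made at the lower rate would call elsewhere were not counted, so the procedure may contribute to this direction. Paired within the 4 animals with both classes, the thinned difference was -1.58, which did not pass (exact permutation p = 0.25, smallest possible 0.125). The 3 stressed animals had fewer peaks in the activated library, at ratios of 0.114, 0.347 and 0.224, and the standard-reared animal had more. Left without stressed non-activated replicate 1, the lists as deposited gave 0.96 in favour of activated libraries (exact permutation p = 0.00794, the smallest possible there and with all 10 libraries). Without that library every activated library was deeper, with shorter fragments, than every non-activated one. The value of 0.96 thus cannot separate activation from depth and library type. At a common background rate the difference without that library was -1.34 (exact permutation p = 0.0476). These tests treat libraries as independent, although 4 animals gave 2 libraries each.

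Rearing was compared first within activated nuclei. Among the strongest peaks, 175 regions were found in all 3 stressed and neither standard-reared library, and 217 in both standard-reared and no stressed library. Of these, 0 of the 175 and 1 of the 217 overlapped no peak in the whole lists of the other group. The whole lists gave 93 and 970. The highest-ranked stressed regions were on chromosome 2 (49887331 to 49887624), chromosome 10 (72922470 to 72922994) and chromosome 9 (45964292 to 45964749). A region on chromosome 10 (128727217 to 128727901) was among the strongest peaks of both standard-reared activated libraries and overlapped no peak of the stressed activated libraries. Further standard-reared regions, from the whole lists, lay on chromosome 13 (78347135 to 78347607), chromosome 1 (88204942 to 88205416) and chromosome 6 (39044108 to 39044434). The total of 392 at equal length was above the other 9 splits into 3 and 2, the highest of which gave 366. On the whole lists another split gave 1282, above the 1063 of the rearing split. Stressed activated libraries had 0.647 times as many peaks (two-sided exact permutation p = 0.2, smallest possible 0.1; n = 3 and 2), a ratio that rested on standard-reared replicate 1: without it the log2 difference was -0.03 instead of -0.63. At a common background rate both standard-reared activated libraries lay above all 3 stressed ones, with a log2 difference of -0.83 (exact permutation p = 0.2), and -0.86 without that replicate.

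Within non-activated nuclei, 55 regions were found among the strongest peaks of all 3 stressed and neither standard-reared library, against 137 the other way. Of these, 2 of the 55 and 0 of the 137 overlapped no peak in the whole lists of the other group. In the whole lists the direction turned, with 91 and 8. Regions on chromosome 14 (47535440 to 47536275) and chromosome 7 (99477299 to 99477721) were among the strongest peaks of all 3 stressed libraries and overlapped no peak of a standard-reared one. On the standard-reared side, regions on chromosome 5 (9346257 to 9346767) and chromosome 11 (96954174 to 96954757) came from the whole lists. The total of 192 lay below those of the other 9 splits, which ranged from 208 to 351. The ratio of peak numbers was 1.76 (two-sided exact permutation p = 0.6; n = 3 and 2), and the log2 difference moved from 0.82 to 0.07 without stressed replicate 1. Averaged per animal over the libraries it gave, stressed and standard-reared mice differed by a ratio of 0.937 (exact permutation p = 1, n = 3 animals each). Only 1 of the standard-reared animals gave both classes, so the activation classes were not balanced in this comparison.

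**Figure D2:**
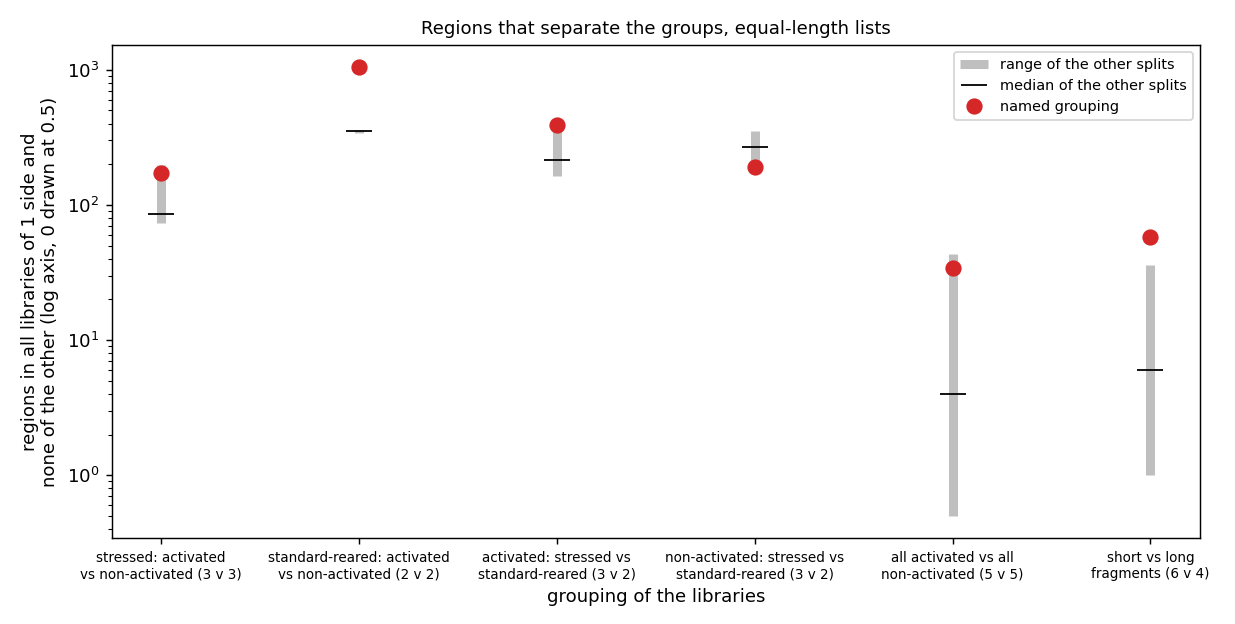
Number of regions, on a log axis, present in all libraries of 1 side and in none of the other at equal list length, for each grouping of the libraries on the horizontal axis; red points show the named grouping, grey bars the range and black lines the median of the other splits of the same libraries. The activated against non-activated grouping gave 34 regions where the highest other split gave 43, and the grouping by fragment length gave 58 where the highest other gave 36.

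Libraries were also compared by the bases they shared. The Jaccard index, shared bases over bases called in either library, ranged from 0.293 to 0.590 over the 45 pairs at equal list length, with a median of 0.477. Pairs of the same activation class had a mean of 0.494 and pairs of different class 0.457 (two-sided exact permutation p = 0.0476; adjusted p = 0.143 over activation, rearing and animal). The 10 activated pairs had a mean of 0.539, whereas the 10 non-activated pairs had 0.449, below the mean of pairs from different classes. Stressed non-activated replicate 1 lowered the latter, with a mean of 0.364 with the other non-activated libraries. Standard-reared non-activated replicate 2 had a mean of 0.538 with the activated libraries, close to that of the activated pairs. Pairs of the same rearing differed from the others by -0.015 (exact permutation p = 0.5), and pairs from the same animal by -0.0086 (exact permutation p = 0.867). The activation difference ranged from 0.0162 without standard-reared activated replicate 1 (exact permutation p = 0.246) to 0.0742 without stressed non-activated replicate 1 (exact permutation p = 0.00794). In the latter setting activation and library type (fragment length and depth) coincided, and similarity by library type was not tested. The activation test regroups libraries freely, although some animals gave a library to each class.

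**Figure D3:**
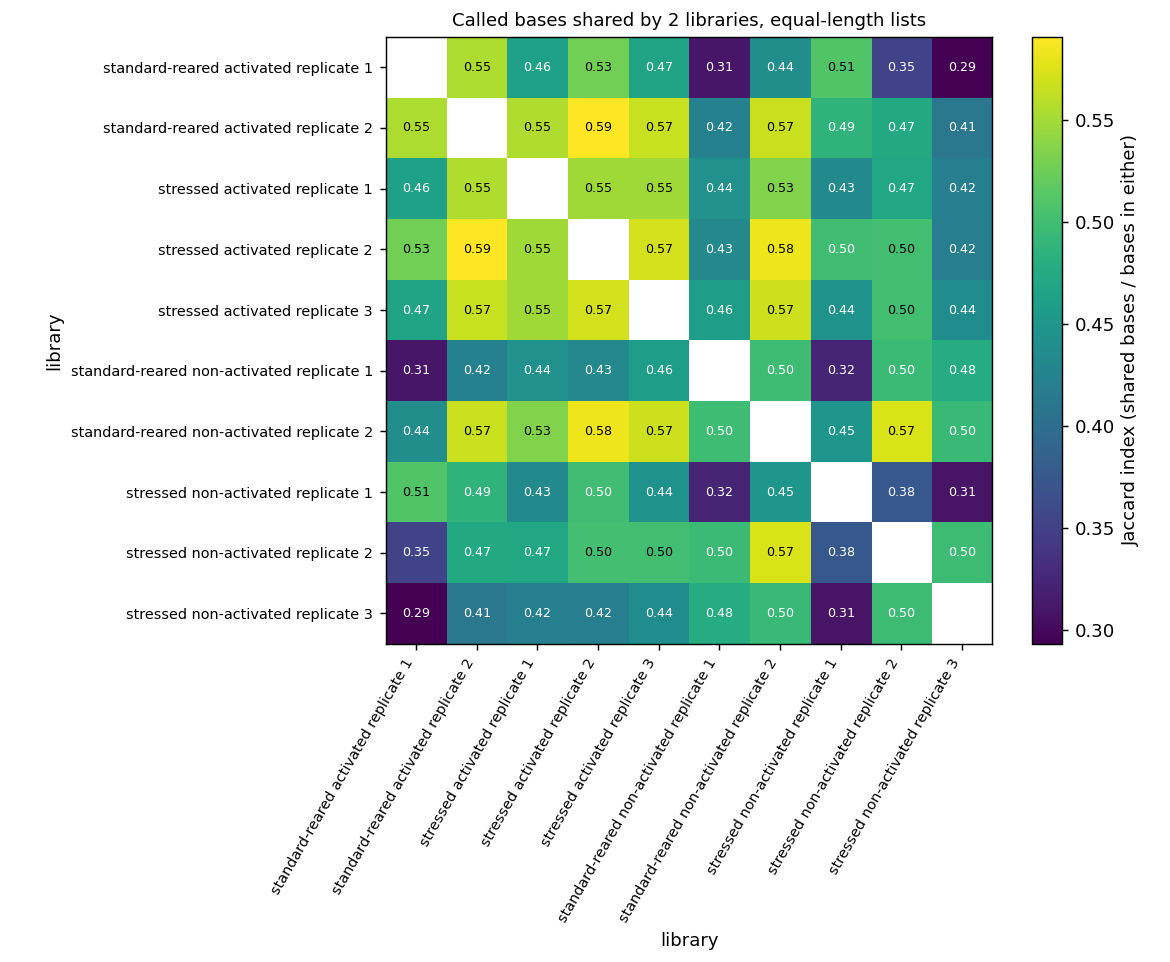
Jaccard index of called bases for each pair of the 10 libraries, named on both axes, at equal list length, as colour and number. The index was highest, 0.590, for standard-reared activated replicate 2 with stressed activated replicate 2, and lowest, 0.293, for standard-reared activated replicate 1 with stressed non-activated replicate 3.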

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

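Some tests were chosen only after the results were seen. They covered the pooled and stressed region counts against other splits, the list length, and swaps within 1 or all animals with both classes. The thinned peak number of stressed non-activated replicate 1 was also set against its label only then, whereas its depth test was written before. Over 8 measures in 2 activation classes 16 groups were searched for a library far from the others, and chance marks about 1 in 20.

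Stressed non-activated replicate 1 stood far above the other 4 non-activated libraries in 4 measures: 50786 peaks (next 14636), 20.3 Mb covered (next 6.30), 6.52 fragments per kb (next 1.45) and 17.7% of peak entries as repeated summits (next 5.02%). Whether depth alone gave this excess of peaks was not settled. Thinned to the background rate of standard-reared non-activated replicate 1 (0.341), the library still held 31643 peaks. The other 4 held at most 14258 at the same p limit without being thinned, but that maximum came from a list with a lower rate (0.238). With all libraries at the lowest background rate the excess was smaller, 12848 peaks against at most 9080. Thinning matched background rates only. With shorter fragments (150 bp against 210 bp or more) the library stayed deeper in fragments per kb. Fragment length cannot decide on a swap with the activated library of the same animal. Both libraries of that animal had short fragments, 134 bp in the activated and 150 bp in the non-activated one. The other non-activated libraries had 210 bp or more, so with or without a swap this animal would differ from them. A single wrong label cannot be told apart from other causes, since the tables point both ways. Its Jaccard index with activated libraries exceeded that with non-activated ones by 0.110, against at most 0.0344 in the other 4, but thinned to the common rate it held 12848 peaks where the 5 activated libraries held 1471 to 3679.

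Standard-reared activated replicate 1 stood above the other 4 activated libraries with 39783 peaks (next 19710) and 15.4 Mb covered (next 8.36). Thinned to the lowest background rate of the activated libraries it kept 21110 peaks against at most 16964, so depth is not the whole of the excess at that rate. At the lowest rate of all 10 libraries it held 3518 peaks and standard-reared activated replicate 2 held 3679. No biological explanation was tested; this library is from a male and the other standard-reared activated one from a female.

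The 34 regions that separated all activated from all non-activated libraries at equal list length were matched or exceeded by 2 of 100 splits into 5 and 5, the real one included, which argues against chance only if libraries of the same animal are taken as independent; the highest other split gave 43. On the whole lists 26 of 100 splits gave as many as the real 7. Of the 16 splits that swap libraries within the 4 animals with both classes, the highest other gave 19 at equal length and 209 on the whole lists, and 16 splits are too few for a share under 0.05. The split with 43 put stressed non-activated replicate 1 in place of stressed activated replicate 2. Library type stays open: the 6 short-fragment libraries against the 4 long-fragment ones gave 58 regions, where the highest other split gave 36. The list length stays open too, since 0 of the 34 regions lacked a peak in every whole list of the other class. Each overlapped a peak in at least 1 of those lists, and in how many was not counted. Activation itself was not tested apart from library type and remains possible. Which cell types each class held was not examined. For the stressed mice alone, 2 of the 10 splits gave as many as the real 173 regions (highest other 197), and 10 splits are too few for a share under 0.05.

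Mitochondrial peaks were outside the comparisons. The local background there, relative to the genome-wide rate, was 80.4 in stressed activated replicate 1 and 146 in stressed activated replicate 3, above the 69.4 that was the highest in standard-reared activated libraries; stressed activated replicate 2 had 65.7. In stressed non-activated replicate 3 it was 1451, above the 179 and 519 of the standard-reared non-activated libraries. Stressed non-activated replicates 1 and 2 had 98.7 and 441, so the stressed libraries lay on both sides. The ratio was 44.2 to 146 in the short-fragment libraries and 179 to 1451 in the long-fragment ones, so it followed library type.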

How the results depend on the processing

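Added after seeing the data were the 50% region coverage, thinning among activated libraries, leaving out both libraries with the most peaks, each library left out for similarity, swaps within animals for the pooled regions, pairing and left-out libraries for the thinned lists, and sex. Of 162 alternative values with a test, 138 kept their direction and side of the threshold. Of 62 alternative region counts, 25 kept their direction and stayed within 1.5 times the count reported, 30 kept it and moved further, and 7 turned. Causes below were not tested, unless the setting removes libraries. Thinned to the lowest background rate, the log2 difference of activated to non-activated turned to -1.54 for peaks (p = 0.0317, exact permutation; 0.00794 to 0.75 over the settings of the peak number) and -1.25 for covered length in all animals, and to -0.44 and -0.023 in standard-reared mice. Leaving out 1 library, the thinned peak difference ran from -1.91 to -1.34 in all animals (exact permutation p from 0.00794 to 0.0476), and in standard-reared mice from -1.34 (without non-activated replicate 1) to 0.46 (without non-activated replicate 2). Counting every summit entry gave 0.12 in stressed mice. Without both libraries with the most peaks, the pooled difference was 0.71 (exact permutation p = 0.0286).

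Leaving out 1 library gave log2 peak differences of -0.58 (without stressed non-activated replicate 3) to 0.67 (without stressed non-activated replicate 1) in stressed mice and 0.25 to 0.96 in all animals. For covered length these ran from -0.63 to 0.69, and from 0.23 to 0.95. For covered length in non-activated nuclei by rearing they ran from -0.0073 (without stressed replicate 1) to 1.36. Similarity by activation ran from 0.0162 to 0.0742, and was 0.0337 on whole lists (exact permutation p = 0.0794). With consensus regions the animal difference turned to 0.0069 and that of sex to -0.0011.

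Regions of 1 group moved most. On whole lists the counts were 62 in stressed mice, 2819 in standard-reared mice, 1063 in activated nuclei by rearing, 99 in non-activated nuclei by rearing and 7 in the pooled comparison. With -log10 q of at least 5 they were 29 (7 activated, 22 non-activated), 1631, 768, 30 and 1. With consensus in 3 or more libraries they were 949 in standard-reared mice and 321 in activated nuclei by rearing, both with the direction turned, and with 50% coverage 1663 in standard-reared mice. Leaving out 1 library gave 306 to 559, 1555 to 2123, 652 to 911, 434 to 726 and 44 to 92, in the same order; fewer libraries then have to meet the rule. Without standard-reared activated replicate 2 the direction turned in standard-reared mice (944 activated, 1042 non-activated) and in activated nuclei by rearing (516 stressed, 395 standard-reared). Of the 65 named regions, 3 were found at equal list length and 30 kept a -log10 q of at least 5.

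Paired within animals (replicate block), the log2 peak difference was -0.08 in stressed mice (n = 3 pairs, exact permutation p = 1) and 0.26 over the 4 animals with both classes (exact permutation p = 0.75, smallest possible 0.125). Covered length gave -0.08 and 0.29, and the stressed region count stayed at 173 (highest other sign change 122). The pooled count of 34 (highest other of 16 swaps 19) went from 2 of 100 splits as large to 1 of 16, and 16 cannot give a share under 0.05. On the thinned lists the block gave -1.58 over the 4 animals (exact permutation p = 0.25), and 4 pairs cannot pass 0.05. The 50% overlap of the shorter interval moved nothing, as merged regions contain their peaks. Those for promoter share, gene lists, list enrichment and motif share were not run. Depth limits the shallow lists.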

Other observations

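The test of regions shared by the stressed activated libraries alone was planned before its result was seen; the position limit on chromosome Y, the test of sex and the tests by chromosome were chosen after seeing the data. Peaks in the first 5 Mb of chromosome Y were called in all 5 male libraries (1, 2, 2, 4 and 3 peaks) and in 0 of the 5 female libraries. Over the whole of chromosome Y the sexes were not separated, with 7, 6, 9, 15 and 9 peaks in male and 7, 4, 1, 1 and 1 in female libraries. One position near 1010290 on chromosome Y was called in 4 of the male libraries, those of the 2 stressed males. Chromosome X held 2.59% ± 0.12 of peaks in female and 2.00% ± 0.44 in male animals (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). At equal list length 3 regions were in all male and no female libraries and 5 the other way, 1 of them on chromosome X (13146774 to 13148291). As many were given by 16 of 100 splits, and the whole lists gave 25 and 0, with 11 of 100 splits as large, so these regions do not set the sexes apart.

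Regions of 1 group were tested for each chromosome by Fisher's exact test, with Benjamini-Hochberg adjustment over chromosomes. In standard-reared mice, 105 of the 2776 regions called in both activated and neither non-activated library lay on chromosome X (3.78%, above the share of all consensus regions; Fisher's exact test, adjusted p = 5.59e-05). At equal list length 6 of 534 such regions did (1.12%), a share below that of the consensus regions (2.29%; Fisher's exact test, adjusted p = 0.506). On the equal-length lists 39 of the 512 regions of the non-activated libraries lay on chromosome 17 (7.62% against 4.56%; Fisher's exact test, adjusted p = 0.0311). Each passed on 1 of the 2 kinds of list only. These were the only passes among 210 tests per kind of list, where 13 at equal length and 8 on the whole lists had an unadjusted p under 0.05. The other comparisons passed 0. The tests take regions, not animals, as units, and cover 2 against 2 libraries in standard-reared mice, where the activated side held a male and the non-activated side did not.

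If stressed activated nuclei carried open regions of their own, more regions would be expected in all 3 of their libraries and none of the other 7 than in other sets of 3. There were 10 such regions at equal list length, and 24 of 100 choices of 3 libraries gave as many, the highest 37. The test does not set stressed activated nuclei apart from a chance choice of libraries, and at this depth it does not show that such regions are absent.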
